A study of Homo sapiens with 4 samples.

How the data were processed

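The series holds 4 microarrays of sorted pancreatic cancer cells, 2 of AsPC1 and 2 of CFPAC. Per the labels' protocols, cells grown in DMEM with fetal bovine serum were stained for acetylated tubulin and sorted by flow cytometry into a high and a low fraction, total RNA was purified on columns, and 400 ng was amplified with oligo-dT primers and labelled with cyanine dyes after RNA spike-ins had been added. Each array carried the AcTub-high fraction in Cy5 and the AcTub-low fraction in Cy3 of one line, with no array of the opposite dye orientation.

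Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 and probe positions are on GRCh37. The deposited scanner files give, per the file headers, the intensity of each spot and of its local background in both channels on a linear scale with no normalization. They also give processed intensities that the authors' software had background-subtracted, spatially detrended and dye-normalized within the array by a linear and lowess fit, and the log10 ratio of red over green made from these. The authors' deposited series table holds one log10 ratio per probe and array; set against the log10 ratio of the scanner file of the same array, its scale, direction and centring were the same, with a slope and correlation of 1 and a median of 0 in each column. Partek is named in the submitters' processing notes without a role. Which program averaged probes that were spotted several times is not given in the sources used here.

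Starting from the deposited mean and local background intensities, background was corrected with normexp and an offset of 50, control spots were given weight 0 in a loess normalization within each array, and log2 ratios were averaged over the spots of a probe. Of 41000 gene probes among 45015 spots per array, 26386 were named by matching their accession to the RefSeq gene table, 2399 by the symbol in the file, 596 by a synonym, and 11619 stayed without a symbol. A probe was kept if it was well above background in red or green on both arrays of at least 1 line, which left 23732 probes. The brightest passing probe stood for each gene, giving 17855 genes. A gene not well above background in 1 fraction on both arrays of a line was given a bound, from the mean normalized brightness of the measured fraction over the lowest signal well above background or the dim signal itself, whichever was higher; without a dye swap such bounds are open to dye bias. The number of arrays limits the precision of all values.

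Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all 4 arrays with a mean per line, with 2 residual degrees of freedom before moderation. The contrasts were the mean ratio of AsPC1, of CFPAC, of both lines, and the difference of CFPAC minus AsPC1. The lines were also compared by the mean log2 brightness of both channels after Aquantile normalization. Adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05. The 38 gene lists covered the cell cycle, histones, ribosomes, proteasome, stress, hypoxia, signalling pathways, metabolism, cilia, tubulins and their modification, mesenchymal and epithelial genes, stem cell genes and cell types (acinar, ductal, endocrine, tuft, fibroblast, immune and neural). They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The preset correlation called 15 lists in AsPC1, 9 in CFPAC, 13 for both lines and 10 for the difference. With an estimated correlation camera called 0 lists in each of these contrasts, and 6, 4, 5 and 5 lists had an unadjusted p under 0.05. That version rests on the 2 residual degrees of freedom of the fit, so that it had little power to call a list. The estimated correlation lay below the preset of 0.01 for lists such as G1 to S (-0.0233) and proteasome (-0.0195). It lay above the preset for others, such as ribosomal proteins (0.1285). For lists below the preset, the lost calls therefore do not show that correlation between members made the calls. For those above it, such as ribosomal proteins, correlation between members can have contributed to the calls. For each list the median was also set against 10000 random lists of the same size matched on brightness in 10 bins, which was chosen after the data were seen. The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

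Genes were named by rule: per contrast the 12 with the largest increase and the 12 with the largest decrease among called genes with a symbol that moved the same way on both arrays, up to 4 members of each list with the smallest p, and always DCLK1, ATAT1, HDAC6, SIRT2 and the alpha-tubulins. Y-linked genes and XIST were left out, and some named genes and 1 gene list are not reported here. Measured error between arrays was compared with spot noise over probes spotted 10 times. Genes with probes at least 100 bases apart were used to compare probes of a gene, and those at least 500 bases apart on one transcript to compare 5' with 3' probes, with bootstrap intervals of 2000 draws at a confidence level of 95%. A regression of each array's ratios on probe GC, target position and brightness with splines of 4 degrees of freedom served as a correction for probe trends.

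The pipeline was tested on simulated data for the AsPC1 contrast, with 17855 genes of which 50 were changed per fold size. It recovered 0% of genes changed 1.1-fold, 48% at 1.25-fold, 78% at 1.5-fold and 92% at 2-fold, with 3 false calls. Few genes were changed in the simulation, whereas 71.1% of genes were called in the AsPC1 data. The adjusted threshold was therefore stricter in the simulation, and these shares do not carry over to the data. The simulated noise was array error only, so the false calls do not speak to differences between cultures. For the CFPAC contrast, with no gene changed, it made 0 calls. Alternatives covered the background correction, offset, within-array and between-array normalization, the filter on dim probes, probes of a gene, the deposited processed ratios and series table, variance moderation, the samples in the fit, a replicate block, the threshold of 0.1 and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and files were read with the data.table package (1.17.8). Exon and untranslated region context of the probes was not analysed here, because no annotation of this genome build was used.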

Results

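Gene expression was compared between cells with much and cells with little acetylated tubulin in AsPC1 and CFPAC, established human pancreatic cancer cell lines. Acetylation of alpha-tubulin is a modification of long-lived microtubules. Cells of each line had been labelled with an antibody against acetylated tubulin (AcTub) and sorted by flow cytometry into a fraction with high and a fraction with low signal. RNA of both fractions was hybridised together on 2-colour Agilent whole-genome arrays, with the AcTub-high fraction in the red dye (Cy5) and the AcTub-low fraction in the green dye (Cy3). The labels name the fractions AAT+ and AAT-, while the sorting protocol speaks of AcTub; AAT+ was read as AcTub-high, and the direction of every ratio rests on that reading. The series held 4 arrays, 2 per line, each made from 400 ng of RNA. Signal was well above the local background at 52.3% to 57.7% of the spots of a channel, and 0 spots were saturated. After a filter on dim probes, 17855 genes were tested, of which 13501 had a gene symbol. All ratios below are AcTub-high over AcTub-low on the log2 scale, so that positive values are higher in the AcTub-high fraction.

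The labels call the arrays of a line biological replicates, and the files were used to measure how far these arrays differed. Over 174 probes that were spotted 10 times each and were bright on all arrays, the variance between the 2 arrays of a line was 1.19 ± 0.119 (SE) times the spot-to-spot variance in AsPC1 and 1.10 ± 0.112 times in CFPAC, where spot noise alone would give 1.06. The same ratio between arrays of different lines was 862. The 2 arrays of a line therefore differed by no more than the spot noise, and they were counted as 1 sample, so that n = 1 per line. Values are means of the 2 arrays, and ± is the SD between them, which measures array error and not the spread between cultures. Adjusted p-values from limma compare these arrays and not the conditions in general, and for that reason sizes of change are given first. Ratios were also relative to the typical gene of each array. RNA spike-ins, which were added before amplification, read 2.56 and 2.58 times their expected red over green ratio on the AsPC1 arrays and 6.14 and 6.11 times on the CFPAC arrays. Scaling to the spike-ins in place of the genes would lower every log2 ratio by a shift of -1.37 in AsPC1 and -2.63 in CFPAC, which would leave 200 genes above 0 in AsPC1 and 5 in CFPAC.

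The first comparison asked which transcripts differed between the sorted fractions of AsPC1. The largest increase was at the probe of CMTR1, an mRNA cap methyltransferase, at 3.31 ± 0.03 or 9.93-fold (limma adjusted p = 1.03e-05; chromosome 6, 37429924 to 37429983, GRCh37). ND3, a mitochondrially encoded subunit of respiratory complex I, was higher by 2.95 ± 0.03, and MUC4, a membrane mucin, by 2.92 ± 0.04 (chromosome 3, 195514780 to 195514839). The secreted protease inhibitor SLPI was 2.25 ± 0.01 higher at one probe and 2.18 at the other. Also higher were AFDN, a junction protein, at 2.63, the small Cajal body RNA SCARNA17 at 2.58, the JNK scaffold MAPK8IP3 at 2.51, MUC8 at 2.47, NPIPB5 at 2.46, the corepressor TLE1 at 2.38, TNRC18 at 2.29 and ZFP41 at 2.26. The decreases were smaller. GINS4, a subunit of the replication complex GINS, was lowest at -1.94 ± 0.08 (adjusted p = 1.93e-05), followed by SPOUT1 at -1.56, the histone chaperone NAP1L4 at -1.43, CDIPT at -1.39, PAQR4 at -1.38, the splicing factor RNPS1 at -1.35, the cell cycle transcription factor MYBL2 at -1.31, MED18 at -1.30, MYADML and the translation elongation factor EEF2 both at -1.29, and REXO4 at -1.26. The olfactory receptor probe of OR4C3 was at -1.38, with an AcTub-high signal that was not well above background. Its bound of 2.61-fold lower was the size of the mean ratio itself and is not a firm lower limit. In total 1676 genes were at least 1.5-fold higher on both arrays, 610 were at least 1.5-fold lower on both, and 0 went opposite ways; with the log ratios of the Agilent software these were 3155 and 2082. Limma called 12686 genes different from 0 at an adjusted p of 0.05, 7170 higher and 5516 lower, with a median absolute change of 0.21 over all genes, and 1504 genes beyond 1.5-fold. Several of the leading genes had another probe with a much smaller or opposite change: 0.09 for AFDN, 0.05 for MAPK8IP3, 0.03 for TLE1, 0.17 for ZFP41, -0.37 for GINS4, -0.08 for the third probe of CMTR1 and 0.59 for the fourth of MUC4. The other probes of AFDN, MAPK8IP3 and ZFP41 were dim, with a mean log2 brightness of 6.42, 6.12 and 6.26. At that brightness the offset of 50 pulls ratios towards 0, so that these probes cannot show disagreement. The CMTR1 probes had a mean log2 brightness of 15.71, 15.21 and 7.73, and the second was at 2.72. With this gap to the third probe, it is uncertain whether the bright probes measure CMTR1. Other probes were at -0.30 and -0.43 for RNPS1 and at 0.92 and 0.75 for NPIPB5. Those of TNRC18 were at 0.96, 1.58 and 2.19. NPIPB5 belongs to a family of near-identical copies, so that its assignment is uncertain.

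Cell cycle genes were lower in the AcTub-high fraction of AsPC1. Of 43 measured genes of the G1 to S transition, 40 were lower and 2 higher past the limma threshold, with a median of -0.55; MCM2, a subunit of the replicative helicase, was at -0.88 ± 0.00, thymidylate synthase TYMS at -0.75, and E2F1 at -0.56. Of 51 genes of G2 and mitosis, 44 were lower and 2 higher (median -0.43), among them the mitotic spindle genes KIF11 at -1.02 ± 0.02, TPX2 at -0.97 and TACC3 at -0.78. Camera with its preset correlation gave adjusted p = 5.18e-12 and 5.28e-11 for these lists, and 0.234 for both as adjusted p with an estimated correlation. Here and below, that version rests on 2 residual degrees of freedom and has little power. For lists with an estimated correlation below the preset, a lost call does not show that correlation between members made the call. For lists above it, such as ribosomal proteins (0.1285), that correlation can have contributed to the call. Genes of ribosome assembly fell as well, with 27 of 33 lower, 4 higher and a median of -0.34 (adjusted p = 6.29e-07), including nucleolin NCL at -0.95, NOLC1 at -0.98 and DKC1 at -0.71. Among 31 proteasome subunits 24 were lower and 4 higher (median -0.28, adjusted p = 3.98e-05), and adjusted over the list alone these were 25 and 5; PSMD3 was at -0.86. Of 20 heat shock genes 13 were lower and 1 higher (median -0.26, adjusted p = 0.000724), with the chaperone partners STIP1 at -0.99 and HSP90AA1 at -0.85. The adjusted p with an estimated correlation was 0.234 for each of these 3 lists.

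Histone genes were higher in AsPC1 at 43 of 45 measured members, with 0 lower and a median of 0.60 (camera adjusted p = 8.45e-10; adjusted p = 0.234 with an estimated correlation), for example H2AC20 at 1.01 and H2BC11 at 0.95. Histone genes are near-identical to each other, so that single members are uncertain. RNA was amplified with oligo-dT primers, and how fully this captured histone transcripts or SCARNA17 was not measured in either line. These values are therefore array signals and need not be transcript amounts. Ribosomal protein genes were higher at 62 of 78 and lower at 2 (median 0.40, adjusted p = 2.05e-08; adjusted p = 0.325 with an estimated correlation), with RPL23 at 1.10 and RPS21 at 0.97, and 63 were higher adjusted over the list alone. The 6 measured mitochondrially encoded genes were all higher (median 1.65, adjusted p = 0.00102; adjusted p = 0.249 with an estimated correlation), among them CYTB at 1.81 and ND5 at 1.48. COX1 was at 1.95, but the file places its probe on chromosome 1 at 567567, not on the mitochondrial genome. Ductal cell markers were higher at 17 of 23 and lower at 3 (median 0.69, adjusted p = 0.000622), with S100P at 1.80, keratin KRT7 at 1.60 and the gel-forming mucin MUC5AC at 1.57. Hypoxia genes were higher at 19 of 25 and lower at 2 (median 0.37, adjusted p = 0.000978), led by ANGPTL4 at 1.75, the glycolysis regulator PFKFB3 at 1.63 and BNIP3 at 1.34. The adjusted p with an estimated correlation was 0.234 for the ductal and hypoxia lists. Targets of NF-kB were higher at 16 of 23 and lower at 4 (median 0.51, adjusted p = 0.0278), with NFKB2 at 1.44 and TRAF1 at 1.07. Acinar markers were higher at 9 of 12 (median 0.20, adjusted p = 0.0361), with CTRB2 at 0.86 and SPINK1 at 0.64. Immediate early genes were lower at 14 of 23 and higher at 7 (median -0.27, adjusted p = 0.0362), with FOS at -0.89 and PPP1R15A at -0.97. The adjusted p with an estimated correlation was 0.325 for the NF-kB, acinar and immediate early lists. The acinar call was lost with the strict filter on dim probes (adjusted p = 0.0514) with the mean of all probes (adjusted p = 0.0685) and after the later correction for probe trends (adjusted p = 0.197), and the immediate early call with the mean of all probes (adjusted p = 0.0756), after that correction (adjusted p = 0.0551) and without either CFPAC array (adjusted p = 0.0511 each). The NF-kB call was lost with the series table (adjusted p = 0.0528). NRF2 targets had a median of -0.10 with 13 of 24 lower and 5 higher (adjusted p = 0.016; adjusted p = 0.31 with an estimated correlation), and TXNRD1 was at -1.08; with median centring the list was not called (adjusted p = 0.0876). Their median lay at percentile 6.3 of 10000 random lists matched on brightness, while those of the acinar and immediate early lists lay at 95.2 and 0.21; the other lists called in AsPC1, tubulins included, lay at 99.85 or higher or at 0.08 or lower.

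The same comparison was made in CFPAC. CMTR1 at 3.16 ± 0.01 or 8.97-fold (limma adjusted p = 1.05e-05), ND3 at 3.12 ± 0.00 and MUC4 at 2.90 ± 0.02 again headed the increases, followed by AFDN at 2.58, SCARNA17 at 2.25, TNRC18 at 2.23, INTS1 at 2.15, FASN, the fatty acid synthase, at 2.10, RAB11B, a small GTPase of recycling endosomes, at 2.06, and NAV2 at 2.04. The histone gene H2BC17 was at 2.16. The probe named HNRNPM was at 2.48, but the file places it on the mitochondrial genome, and the other HNRNPM probe was at -0.48. Among the decreases, PSMC3, an ATPase of the proteasome, was at -2.44 ± 0.01 (adjusted p = 1.05e-05; chromosome 11, 47444434 to 47444493), the centromere chaperone HJURP at -2.39 ± 0.06 and the flap endonuclease FEN1 at -2.24 ± 0.04, with its other probe at -1.39. AHSA1, an activator of the HSP90 chaperone, was at -2.18, P3H4 at -2.09, EEF2 at -2.03, RPN2 at -1.95, GINS4 at -1.91 and RAB8A at -1.90. ACTL8 was lower by a bound of 5.10-fold, the same size as its mean ratio of -2.35, with an SD between arrays of 0.59. That bound is therefore a mean and not a firm lower limit. On both arrays 1398 genes were at least 1.5-fold higher, 1293 were at least 1.5-fold lower, and 0 went opposite ways; with the log ratios of the Agilent software these were 3486 and 2785. Limma called 12787 genes, 6632 higher and 6155 lower, with a median absolute change of 0.22, and 2019 genes beyond 1.5-fold. With median centring in place of loess, 893 genes were at least 1.5-fold higher and 2181 lower, and limma called 5624 higher and 7667 lower, so that the balance of directions depended on the scaling. Other probes were at 0.13 for GINS4, -0.05 for AFDN (a dim probe), -0.45 for RAB8A, -0.45 for the third probe of CMTR1 and -0.29 for the fourth of MUC4. Those of TNRC18 were at 0.65, 0.72 and 1.67, and those of NAV2 at 0.62, 1.04, 0.54 and -0.10.

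**Figure D1:**
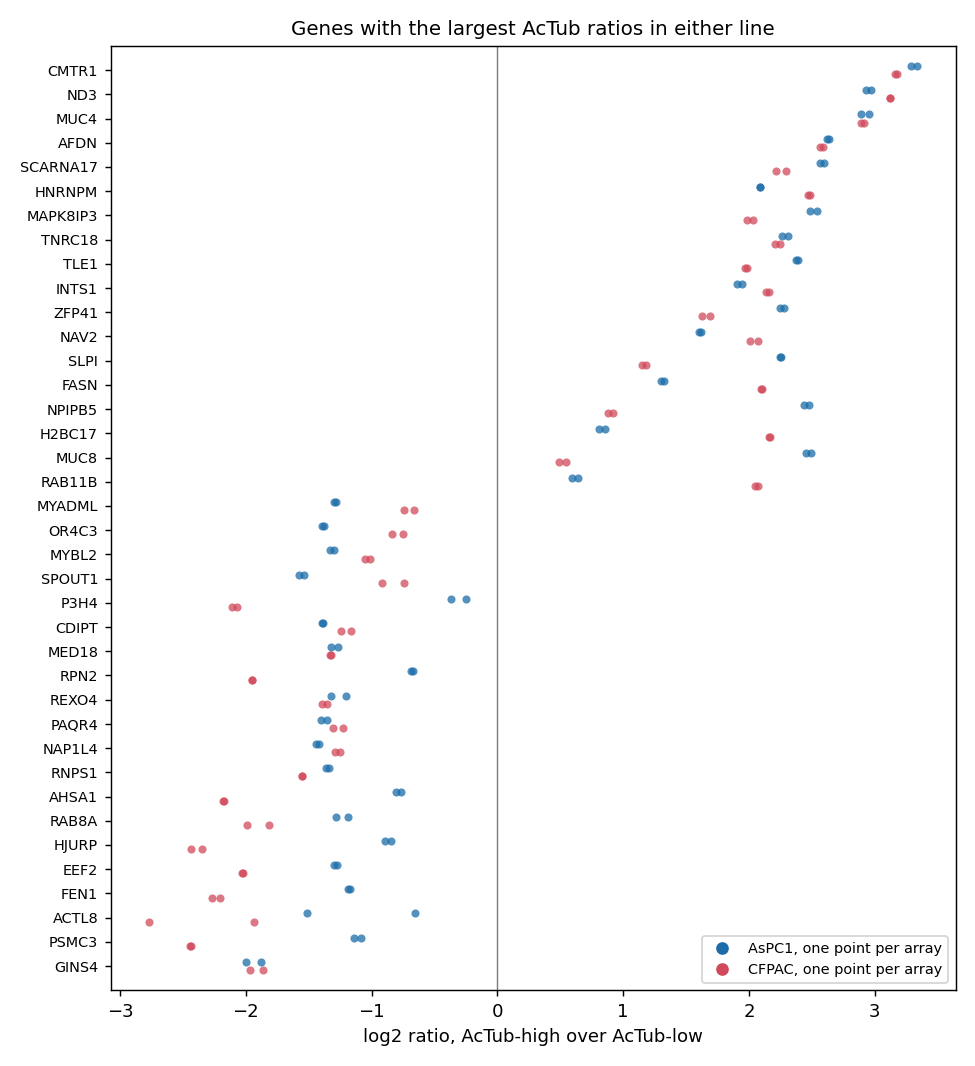
Log2 ratio, AcTub-high over AcTub-low (horizontal axis), of the reported genes with the largest ratios in either line, with 1 point per array, blue for AsPC1 and red for CFPAC. CMTR1 lay at 3.31 in AsPC1 and 3.16 in CFPAC, GINS4 at -1.94 and -1.91, and RAB11B at 0.62 and 2.06.

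Of the gene lists, 9 were called by camera in CFPAC, each in the direction seen in AsPC1, and the adjusted p with an estimated correlation was 0.369 for 8 of them and 0.675 for the ribosomal protein list. Histone genes were higher at 42 of 45 and lower at 1 (median 0.74, adjusted p = 3.17e-11), with H3C3 at 1.57 and H2BC11 at 1.23; adjusted over the list alone 43 were higher. Proteasome subunits were lower at 26 of 31 and higher at 3 (median -0.59, adjusted p = 4.94e-06), with PSMD2 at -1.47 and PSMD3 at -1.30. Ribosome assembly genes were lower at 26 of 33 and higher at 6 (median -0.37, adjusted p = 0.000219), with NOLC1 at -1.15 and NOP2 at -1.10. Ribosomal protein genes were higher at 53 of 78 and lower at 16 (median 0.21, adjusted p = 0.00147), or 54 and 17 adjusted over the list alone; RPL28 was at 1.00 and RPL26 at -0.67. The G1 to S list was lower at 30 of 43 and higher at 6 (median -0.29, adjusted p = 0.00152), with NASP at -1.56 and MCM2 at -1.22, while UHRF1 was at 1.12. The list of G2 and mitosis was lower at 28 of 51 and higher at 10 (median -0.14, adjusted p = 0.0192), or 29 and 10 adjusted over the list alone, with TPX2 at -1.46 and TACC3 at -1.14. All 6 mitochondrially encoded genes were higher (median 0.94, adjusted p = 0.00585). Ductal markers were higher at 17 of 23 and lower at 4 (median 0.30, adjusted p = 0.00585), with KRT7 at 1.99 and S100P at 1.10. NRF2 targets were lower at 17 of 24 and higher at 4 (median -0.34, adjusted p = 0.00585), with PRDX1 at -0.79, while ferritin heavy chain FTH1 was at 1.24. The median of the list of G2 and mitosis lay at percentile 4.68 of the random lists, and those of the other called lists at 0.1 or lower or at 99.73 or higher. After correction of the ratios for probe GC, target position and brightness, an analysis added after the data were seen, camera no longer called the ribosomal protein list (adjusted p = 0.787) or the list of G2 and mitosis (adjusted p = 0.295) in CFPAC. Medians that fell by over 1.5 times but stayed called were 0.18 for ribosomal proteins and -0.05 for NRF2 targets in AsPC1, and -0.14 for G1 to S and -0.20 for NRF2 targets in CFPAC. With the log ratios of the Agilent software the ribosomal protein list had an adjusted p of 0.0781 in CFPAC.

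**Figure D2:**
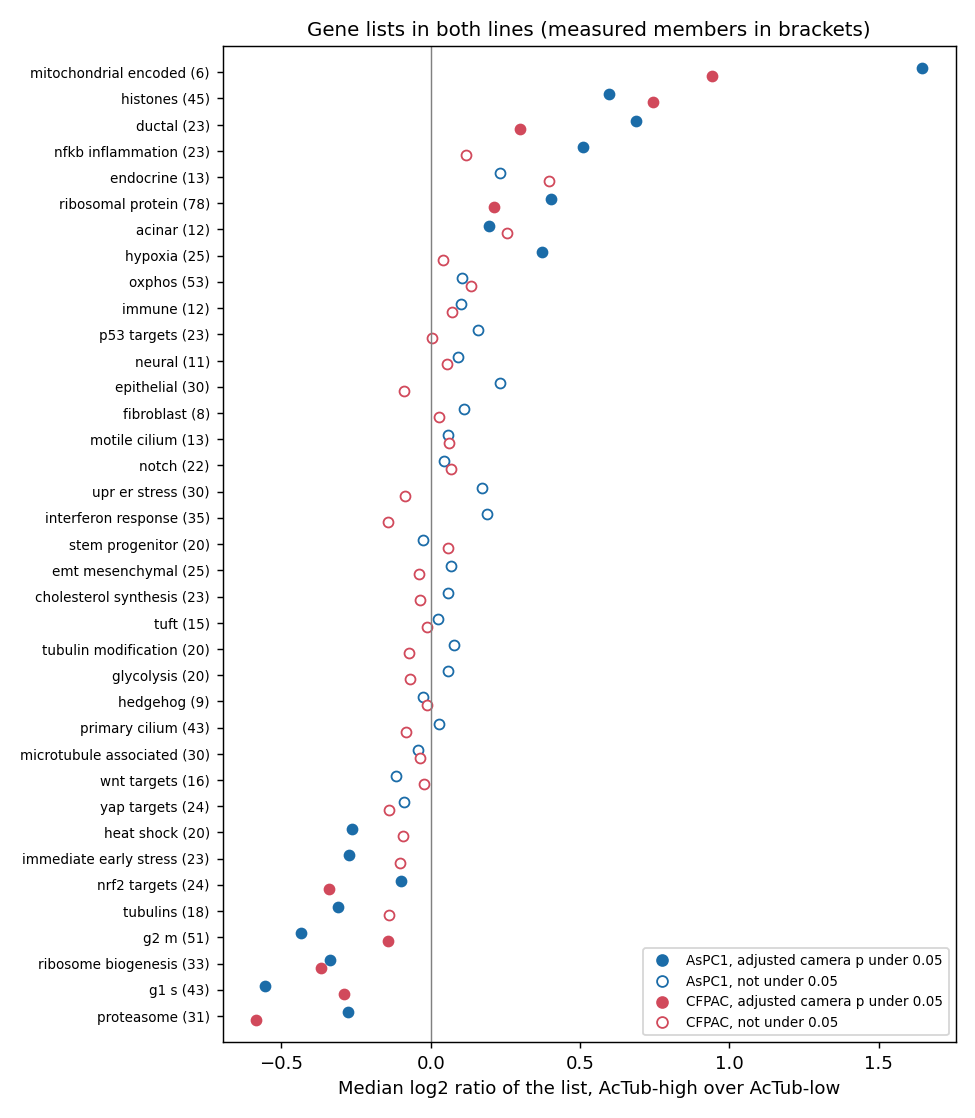
Median log2 ratio, AcTub-high over AcTub-low (horizontal axis), of the measured members of each gene list reported here, with 1 point per line, blue for AsPC1 and red for CFPAC; filled points have a camera adjusted p under 0.05. The G1 to S list had a median of -0.55 in AsPC1 and -0.29 in CFPAC, and the histone list 0.60 and 0.74.

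The effects in both lines were then set side by side. Averaged over the lines, limma called 14067 genes, 7630 higher and 6437 lower. Across genes, the log ratios of the 2 arrays of a line correlated at 0.977 in AsPC1 and 0.977 in CFPAC, and those of arrays from different lines at 0.698 to 0.70, where genes are not independent replicates. The sign of the change was the same in both lines for 75.9% of the genes. Of the genes at least 1.5-fold higher in each line 818 were shared, where independent lists would share 131, and of those lower 386 were shared, where independent lists would share 44.2. Only 10 genes were higher in AsPC1 and lower in CFPAC at this size, and 0 were the reverse. When each line was taken as 1 replicate, a fit added after the data were seen, limma called 710 genes, 533 higher and 177 lower. The dyes were never exchanged, so that a dye effect of a probe would appear as the same change in both lines. Among 4287 genes with another probe at least 100 bases away, the averaged ratios of the probes correlated at 0.315 (95% interval 0.287 to 0.341) and had the same sign in 60.2%. The other probe was the dimmer one, and the offset of 50 pulls dim ratios towards 0, which can lower this agreement without a dye effect. Of 765 genes with such a probe that were at least 1.5-fold changed in AsPC1, 553 (72.3%) had the same sign and 178 (23.3%) the same change of at least 1.5-fold at the other probe. In CFPAC these were 545 (64.7%) and 162 (19.2%) of 843. The other probe changed at least 1.5-fold the opposite way at 14 of these genes in AsPC1 and 49 in CFPAC. A pull towards 0 alone cannot give these opposite changes.

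**Figure D3:**
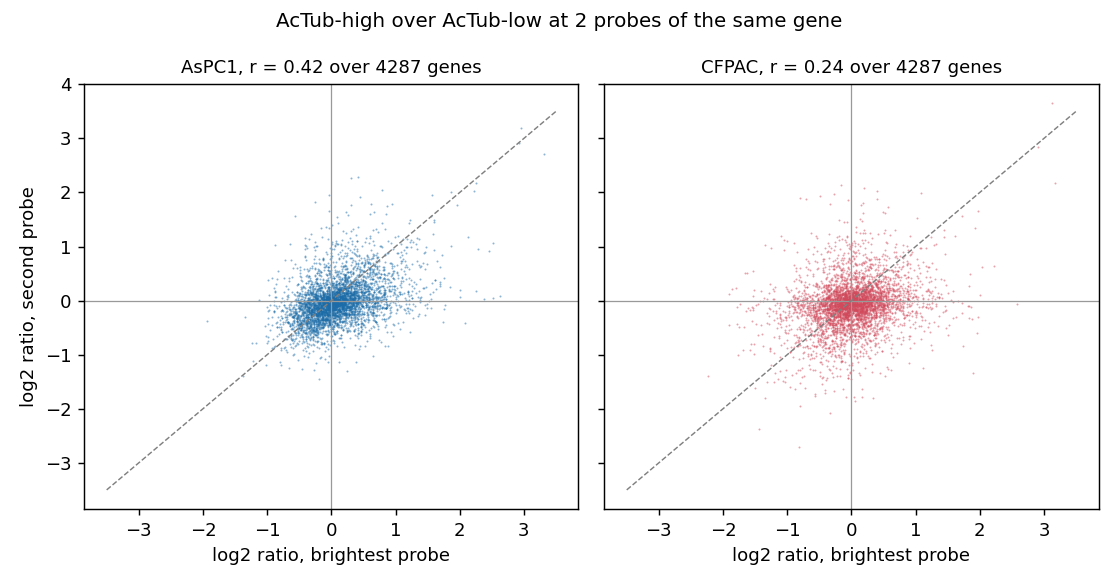
Log2 ratio, AcTub-high over AcTub-low, at the brightest probe of a gene (horizontal axis) and at another probe at least 100 bases away (vertical axis), with 1 point per gene, for AsPC1 (left) and CFPAC (right); the dashed line marks equal ratios. The ratios of the 4287 genes correlated at 0.42 in AsPC1 and 0.244 in CFPAC. The other probe was the dimmer one.

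The enzymes that set tubulin acetylation and the alpha-tubulin genes were examined in both lines. ATAT1, the alpha-tubulin acetyltransferase, was at -0.31 ± 0.12 in AsPC1 (limma adjusted p = 0.0294) and at -0.11 ± 0.23 in CFPAC, where it did not pass the threshold (adjusted p = 0.326). Its other probe was at -0.01 in AsPC1 and -0.25 in CFPAC, and the AsPC1 call was lost without either AsPC1 array (adjusted p = 0.057 and 0.19). The ATAT1 probes had a mean log2 brightness over all arrays of 6.27 and 6.17, near background. At that brightness the offset of the background correction pulls ratios towards 0. The size of any ATAT1 change is therefore uncertain in both lines, and the small values do not show that ATAT1 was unchanged. HDAC6, the main tubulin deacetylase, was at 0.53 ± 0.00 in AsPC1 and -0.19 ± 0.03 in CFPAC (adjusted p = 7.87e-05 and 0.00227), and the difference between lines was -0.72 ± 0.04 (SE, adjusted p = 0.00031). SIRT2, another tubulin deacetylase, was at 0.09 in AsPC1, not past the threshold, and at 0.18 ± 0.10 in CFPAC. With median centring the CFPAC value turned to -0.06, and SIRT2 was called in AsPC1 (0.11) and for the difference (-0.17). Of 18 tubulin genes 14 were lower and 0 higher in AsPC1 (median -0.31, camera adjusted p = 0.000365; adjusted p = 0.234 with an estimated correlation). In CFPAC 10 were lower and 7 higher (median -0.14, adjusted p = 0.552), or 10 and 8 adjusted over the list alone; with the mean of all probes the list was called there too (median -0.21, adjusted p = 0.0488). Among alpha-tubulins in AsPC1, TUBA1A was at -0.55, TUBA1B at -0.52, TUBA1C at -0.54, TUBA3C at -0.39, TUBAL3 at -0.42, TUBA4A at -0.20 and TUBA8 at -0.18, whereas TUBA3D was at 0.10 and did not pass. In CFPAC TUBA1C was at -0.43, TUBA3C at -0.29, TUBA4A at -0.17 and TUBAL3 at -0.11, while TUBA8 at 0.23, TUBA3D at 0.27 and TUBA1B at 0.12 were higher and TUBA1A at 0.07 did not pass. The other CFPAC probes were at -0.09, 0.23 and -0.25 for TUBA1C and at -0.29, -0.24 and -1.02 for TUBA4A. The other TUBA3D probe was at -0.45 in AsPC1 and -0.48 in CFPAC, and with the mean of all probes TUBA3D was called lower in both (-0.18 and -0.10). With median centring TUBA3D was called higher in AsPC1 (0.21), the calls of TUBA4A (-0.05) and TUBA8 (-0.06) in AsPC1 and of TUBA1B (0.02) and TUBAL3 (-0.08) in CFPAC were lost, and TUBA1A in CFPAC was at -0.05. The beta-tubulin TUBB was at -0.69 and -1.19, and the gamma-tubulin TUBG1 at -0.59 and -1.43, in AsPC1 and CFPAC. These genes are close in sequence, so that single alpha-tubulins are uncertain. Tubulin-modifying enzymes as a list had medians of 0.08 in AsPC1 and -0.07 in CFPAC and were not called (adjusted p = 0.901 and 0.857). DCLK1, a microtubule-binding kinase used as a marker of tuft cells, was at -0.16 ± 0.02 in AsPC1 (adjusted p = 0.00657; chromosome 13, 36345508 to 36345567), and this probe was not well above background in either fraction of CFPAC. The mean log2 brightness of this probe over all arrays was 6.15, near background, so that its small AsPC1 change is uncertain. The other 3 DCLK1 probes were not well above background on any array.

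Markers of other cell types that the lines might hold were compared in the same way. Tuft cell markers had medians of 0.03 in AsPC1 and -0.01 in CFPAC (15 genes, adjusted p = 0.873 and 0.94). Endocrine markers had medians of 0.23 and 0.40 (13 genes, adjusted p = 0.0771 and 0.196), fibroblast markers 0.11 and 0.03 (8 genes, 0.84 and 0.98), immune markers 0.10 and 0.07 (12 genes, 0.901 and 0.93) and neural markers 0.09 and 0.06 (11 genes, 0.916 and 0.99). Acinar markers in CFPAC had a median of 0.26 (adjusted p = 0.116), but were called with the log ratios of the Agilent software (median 0.72, adjusted p = 0.0484), with median centring (adjusted p = 0.0315) and with no filter on dim probes (adjusted p = 0.0316). Stem and progenitor genes had medians of -0.02 and 0.06 (adjusted p = 0.84 and 0.658). The list was not called in either line for endocrine, fibroblast, immune, neural, tuft or stem genes, and single members past the threshold in AsPC1 numbered 10, 6, 7, 3, 8 and 19. The endocrine list was called under some alternatives, such as no filter on dim probes in AsPC1 (adjusted p = 0.0129) and median centring in CFPAC (adjusted p = 0.0229).

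The difference of the AcTub effect between the lines, CFPAC minus AsPC1, is the contrast in which a dye effect common to all arrays cancels. The largest differences were mostly in genes with a higher ratio in AsPC1. The vitamin B12 carrier TCN1 differed by -2.14 ± 0.04 (SE, limma adjusted p = 0.00018), from 2.02 to -0.12. The channel gene TRPM6 was at 2.13 in AsPC1 and not well above background in either fraction of CFPAC, so that no difference is given. Its other AsPC1 probes were at 1.18, 0.52 and 0.12. Osteopontin SPP1 went from 0.91 to -1.15, the small GTPase RHOV from 0.51 to -1.50, complement C3 from 1.62 to -0.29, HLA-B from 1.11 to -0.67, ceruloplasmin CP from 1.88 to 0.15 and MUC8 from 2.47 to 0.52. MUC17 was at 1.70 in AsPC1, with its other probes at 0.35, 1.37 and 0.10, while its AcTub-low fraction of CFPAC was not well above background. DYRK1A, SNRPN and P3H4 were at 0.05, 0.04 and -0.31 in AsPC1 and at -1.65, -1.65 and -2.09 in CFPAC, but the other DYRK1A probes were at 0.51 and 0.03 in CFPAC. In the other direction UPK3B went from 0.56 to 2.01, RAB11B from 0.62 to 2.06, ADISSP from 0.25 to 1.55, TCF19 from 0.16 to 1.41, NOS3 from -1.11 to 0.10 and NUTM2D from -1.19 to 0.01. POTEM, POTEE and POTEKP, at 1.96, 1.83 and 2.02 in CFPAC, and the histone genes H2BC17 and H2AC14, at 2.16 and 1.93, belong to families of near-identical sequences and are uncertain. TPGS2 went from 0.53 to 1.72, while its other probes were at -0.05 and -0.13 in CFPAC. Limma called 9128 genes, 3719 with a higher and 5409 with a lower value in CFPAC, and 622 beyond 1.5-fold. Without variance moderation 5252 genes were called.

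Of the gene lists, 10 differed between the lines by camera. Some alternatives called further lists. NF-kB targets were called with median centring (adjusted p = 0.0146), no filter on dim probes (0.00644) and the mean of all probes (0.0281). Mitochondrially encoded genes were called with median centring (0.0443), no background subtraction (0.0485) and no filter on dim probes (0.006). The ductal, glycolysis and unfolded protein response lists were called with no filter on dim probes (0.02, 0.0362 and 0.0102). Hypoxia genes differed by a median of -0.44, with 19 of 25 lower in CFPAC and 2 higher (adjusted p = 0.000167), for example the secreted factor STC2 at 0.59 in AsPC1 and -0.56 in CFPAC. Interferon response genes differed by -0.34, with 24 of 35 lower and 3 higher (adjusted p = 0.000163), or 25 and 3 adjusted over the list alone; ISG15, a ubiquitin-like interferon product, was at 1.11 and -0.17 and the transcription factor IRF1 at -0.40 and -1.82. Neither line alone was past the threshold for this list (medians 0.19 and -0.14, adjusted p = 0.054 and 0.226), but alternatives called it in AsPC1 (no filter on dim probes, adjusted p = 0.00642; without the second AsPC1 array, adjusted p = 0.0363; corrected for probe trends, adjusted p = 0.0182) and in CFPAC (median centring, adjusted p = 0.0439). Proteasome subunits differed by -0.31, with 25 of 31 lower and 3 higher (adjusted p = 0.000163), or 26 and 4 adjusted over the list alone. For the hypoxia, interferon and proteasome lists the adjusted p with an estimated correlation was 0.319. Epithelial genes differed by -0.23 (20 of 30 lower, 6 higher, adjusted p = 0.0193), with the membrane protease PRSS8 at 1.12 and -0.29 and MAL2 at 0.97 and -0.14. Primary cilium genes differed by -0.17 (21 of 43 lower, 4 higher, adjusted p = 0.0319), with BBS4 at 0.29 and -0.58 (-0.06 and -0.71 with the mean of all probes) and IFT46 at -0.06 and -0.85, and mesenchymal genes by -0.11 (13 of 25 lower, 2 higher, adjusted p = 0.0369), with LOXL2 at 0.51 and -0.26. The adjusted p with an estimated correlation was 0.428 for these 3 lists. Adjusted over the list alone, 22 primary cilium genes were lower and 3 mesenchymal genes higher. The epithelial call was lost after correction for probe trends (adjusted p = 0.063). The primary cilium call was lost with the mean of all probes (adjusted p = 0.0934), with the log ratios of the Agilent software (adjusted p = 0.0848) and without the second CFPAC array (adjusted p = 0.0601). The mesenchymal call was lost with median centring (adjusted p = 0.0862), after correction for probe trends (adjusted p = 0.0675), with a replicate block (adjusted p = 0.0508) and without 1 array of either line (adjusted p = 0.0623 and 0.0727). Histone genes differed by 0.25 (26 of 45 higher, 7 lower, adjusted p = 0.000163; adjusted p = 0.428 with an estimated correlation) and ribosomal protein genes by -0.18 (45 of 78 lower, 17 higher, adjusted p = 0.0353; adjusted p = 0.792 with an estimated correlation), a call that was lost with the strict filter on dim probes (adjusted p = 0.0618), after correction for probe trends (adjusted p = 0.157), with a replicate block (adjusted p = 0.0508) and without single arrays (adjusted p = 0.0592 to 0.0623). The G1 to S list differed by 0.19 (26 of 43 higher, 6 lower, adjusted p = 0.000163) and the list of G2 and mitosis by 0.17 (27 of 51 higher, 8 lower, adjusted p = 0.000298), with PLK1 at -0.34 and 0.34; both had an adjusted p of 0.319 with an estimated correlation. With median centring in place of loess the medians of the cell cycle lists turned to -0.03 and -0.11, and that of the histone list was 0.03. The median of all genes moved by 0.07 in AsPC1 and -0.11 in CFPAC, a shift too small to account for the whole turn of the cell cycle lists. Camera, which compares a list with the other genes, kept its direction and call (adjusted p = 0.00708 for both cell cycle lists).

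With both fractions averaged, the lines themselves were compared. LGALS2, a galectin, was 289-fold lower in CFPAC than in AsPC1 (limma adjusted p = 1.32e-08), the tetraspanin TSPAN8 91.5-fold, the galectin LGALS4 72.7-fold and the liver and gut transcription factor CREB3L3 46.3-fold. PKDCC, MYO1A, ARPC1B, CDHR2 and GPER1 were 32.4-fold to 40.6-fold lower. The intestinal surface antigen GPA33 and MUC17 were lower too, with no fold given because 1 fraction of CFPAC was not well above background, and the nuclear receptor NR0B2 was at least 36.3-fold lower because CFPAC was not well above background. Higher in CFPAC were the interferon-induced genes IFI27 (11.9-fold), IFI6 (8.46-fold) and MX1 (7.39-fold), the chemokine CXCL1 (10.5-fold), ADH1C (10.3-fold), SPRR3 (10.3-fold), ANXA10 (7.08-fold), H3C8 (6.98-fold), BTBD6 (6.88-fold), KRT7 (5.75-fold), AFAP1L2 (5.60-fold) and GAMT (5.60-fold). Limma called 12903 genes, 7001 higher and 5902 lower in CFPAC, and 1624 differed by over 2-fold. With array medians in place of Aquantile 4351 were higher and 8421 lower. All arrays lay on 1 slide, and array position and line could not be told apart.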

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

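Of the tests in this part, the correction for probe trends with its tests of single lists and the fit for changes beyond 1.5-fold were chosen after the results were seen. All results listed here were picked because the AcTub effect differed between the lines in a test of the difference itself, CFPAC minus AsPC1, and these tests measure array error at n = 1 per line.

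Limma called 9128 genes different between the lines, and camera 10 lists: G1 to S 0.19, G2 and mitosis 0.17, histones 0.25, proteasome -0.31, interferon response -0.34, hypoxia -0.44, epithelial -0.23, primary cilium -0.17, ribosomal proteins -0.18 and mesenchymal genes -0.11. With an estimated correlation camera called 0 lists for the difference, with a lowest adjusted p of 0.319. That version had little power at 2 residual degrees of freedom. The genes below differed beyond 1.5-fold by limma. A lower effect in CFPAC was seen for MUC8 -1.95, MUC1 -1.57, MUC5AC -1.16, SLPI -1.08, AGR2 -1.35, TCN1 -2.14, SPP1 -2.06, C3 -1.91, CP -1.73, MAL2 -1.11, PRSS8 -1.41, LOXL2 -0.78, RHOV -2.01, NPIPB5 -1.56, P3H4 -1.78, DYRK1A -1.71, SNRPN -1.69, VIM -0.78 and BBS4 -0.86. The same direction held for HLA-B -1.78, ISG15 -1.28, IRF1 -1.42, BST2 -0.95 and TRAF1 -0.92, and for STC2 -1.16, ANGPTL4 -1.06, NDRG1 -1.01 and BNIP3 -0.85. PSMC3 differed by -1.33, PSMD2 by -0.83, HJURP by -1.52, FEN1 by -1.06, NASP by -0.92, AHSA1 by -1.39, RPN2 by -1.27 and RPL26 by -0.78. COX1, whose probe the file places on chromosome 1, and the mitochondrial CYTB differed by -0.90 and -0.89, and H2AC7 by -1.18.

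Higher effects in CFPAC were seen for H2BC17 1.33, H2AC14 1.25, H3C3 0.97, POTEM 1.48, POTEKP 1.41, POTEE 1.35, UPK3B 1.45, RAB11B 1.44, ADISSP 1.31, TCF19 1.25, NOS3 1.21, NUTM2D 1.19, TPGS2 1.19, FTH1 1.03, UHRF1 0.92 and FASN 0.79.

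The AcTub effects were alike in the lines, with between-line correlations of 0.698 to 0.70 across genes. Fragmented RNA in the AcTub-high fraction would lower the 5' probe of a gene relative to its 3' probe, but the median of that difference over 2646 genes was 0.0942 in AsPC1 (95% interval 0.0765 to 0.117) and 0.0196 in CFPAC, which argues against fragmentation. A dye effect of single probes may contribute: the averaged ratios of different probes of a gene correlated at 0.315, between the value under 0.2 set for a dye effect and the value over 0.4 set against one, so that a dye effect and a shared effect of AcTub sorting cannot be told apart. The other probe was also the dimmer one, which can lower that correlation without a dye effect. Among genes changed at least 1.5-fold, the other probe did the same at 178 in AsPC1 and 162 in CFPAC. At 14 and 49 it changed by that size the opposite way, which a pull towards 0 alone cannot give. Exchanging the fractions on some arrays gave 8 arrangements, of which 1, the real one, called 14067 genes; the highest of the others, which turned both CFPAC arrays, called 9128, and so few arrangements cannot give a share under 0.05. A difference between cells sorted for AcTub remains open and untested by a dye swap.

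Camera with its preset correlation called 9 lists in both lines, and with an estimated correlation 0 in either, and a trend of the ratios with probe GC, target position and brightness was weighed as their cause. Correction for the trend left 66.7% of these lists with at least 50% of their median shift and a call in both lines, fewer than the 3 of 4 set in advance. Each list was then taken by itself in each line, as its median less that of all genes after the correction. In AsPC1 and CFPAC it was 0.43 and 0.29 for ductal markers, -0.53 and -0.16 for G1 to S (-0.59 and -0.30 before), 0.36 and 0.63 for histones, 1.60 and 1.00 for mitochondrially encoded genes, -0.11 and -0.22 for NRF2 targets (-0.14 and -0.35 before), -0.35 and -0.55 for the proteasome and -0.39 and -0.32 for ribosome assembly. In AsPC1 it was also -0.43 for the list of G2 and mitosis and 0.126 for ribosomal proteins (-0.47 and 0.36 before). In all of these the bootstrap interval over members left out 0 and camera still called the list, which argues against the trend as the whole cause of these shifts. The intervals take members as independent and do not measure the spread between cultures. In AsPC1 the argument is weak for ribosomal proteins, whose estimated correlation was 0.1285. It is also weak there for NRF2 targets, whose uncorrected median lay at percentile 6.3 of the random lists. In CFPAC the ribosomal protein shift fell from 0.20 (95% interval 0.12 to 0.30) to 0.0249 (-0.04 to 0.11) and its call ended because little of the shift was left (adjusted p = 0.787), so that the trend is a candidate explanation there. The shift of the list of G2 and mitosis in CFPAC went from -0.16 (-0.25 to -0.06) to -0.12 (-0.26 to -0.01), and its call ended (adjusted p = 0.295) although the interval left out 0, so that the trend stays open for that list in CFPAC.

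Spike-ins read above their expected red over green ratios, by 2.56-fold and 2.58-fold in AsPC1 and 6.14-fold and 6.11-fold in CFPAC. More fragmentation in CFPAC would lower the 5' probes there, and the difference between lines was -0.0791 (95% interval -0.0961 to -0.0624), above the limit of -0.1. The interval left out 0 on the side that more fragmentation would give, so that a smaller difference in fragmentation between the lines stays open. A smaller amount of amplifiable RNA in the AcTub-high fraction, unequal spike-in volumes, or a difference in labelling or scanning between the dyes was not tested, and no biological explanation was tested.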

How the results depend on the processing

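The alternatives that take each line as 1 replicate, test for changes beyond 1.5-fold or correct for probe trends, and the random-list percentiles, were chosen after the results were seen; the others were planned. The cause of the changes below was not tested, except that the test beyond 1.5-fold asks for larger changes and the filters and left-out arrays change how many genes or arrays enter. Of counts and correlations under the alternatives, 97 stayed within 1.5 times or 1 SD of the reported value. Of values of named genes 8169 kept their direction and side of the threshold, 339 lost and 92 gained a call, and 30 changed sign; of list values 1418 were the same, 29 lost and 32 gained a call and 0 changed their camera direction, while with median centring the medians of the G1 to S and G2 and mitosis differences turned to -0.0318 and -0.106, still called (adjusted p = 0.00708 each). Testing beyond 1.5-fold left 1504 genes in AsPC1, 2019 in CFPAC, 1703 for both and 622 for the difference, taking lines as replicates left 710, and without variance moderation the difference had 5252. With the Agilent processed ratio, genes at least 1.5-fold on both arrays numbered 5237 in AsPC1 and 6271 in CFPAC. Correlations between arrays of AsPC1, of CFPAC and between lines were 0.975, 0.981 and 0.703 without background subtraction, 0.899, 0.902 and 0.657 with the processed ratio, 0.976, 0.979 and 0.669 with median centring, 0.948, 0.951 and 0.677 with no filter on dim probes, and 0.984, 0.985 and 0.713 with the strict filter. Median centring shifted the median of all genes by 0.07 in AsPC1 and -0.11 in CFPAC; 67.3% of AsPC1 calls were then higher (56.5% with loess), 42.3% of CFPAC calls (51.9% with loess) and 13.3% of difference calls (40.7% with loess). With array medians in place of Aquantile, 34.1% of calls between lines were higher in CFPAC (54.3% with Aquantile). Leaving out each array in turn gave 10410 to 12891 genes in AsPC1, 11235 to 12462 in CFPAC, 12947 to 13465 for both, 6787 to 7896 for the difference and 11715 to 12255 for levels, with the lone array of a line assumed to vary like the other line. With the replicate number as a block, 12709 genes were called in AsPC1, 12728 in CFPAC, 14056 for both, 8831 for the difference and 13062 for levels; deviations of same-numbered arrays correlated at 0.003 between lines, so the numbers name arrays and do not pair them. Called values that changed sign were the following. For the difference, NAP1L4 went to -0.0643 (processed ratio and series table), -0.0088 (offset 0) and -0.0507 (median centring), and TUBAL3 to -0.222 (processed ratio and series table). Median centring gave PRDX1 0.0488 in AsPC1, CP -0.104, SIRT2 -0.0641 and H2AC7 -0.139 in CFPAC, and for the difference ND3 -0.118, CDIPT -0.0671, INTS1 -0.072, TUBA1C -0.169, PPP1R15A -0.136 and TRPM5 -0.0661. The mean of all probes gave TPGS2 -0.108, HSPA8 -0.0644 and BBS4 -0.058 in AsPC1, HSPA8 -0.0844, TUBA3D -0.105, POU5F1 -0.0663 and NDRG1 0.586 in CFPAC, and HSPA8 -0.0201 and H2AC20 0.131 for the difference. The correction for probe trends gave NOS3 -0.0355, TCN1 0.0412, TUBAL3 0.0031, H2AC7 -0.0405 and MAL2 0.0052 in CFPAC. Signal over background limited the values of dim genes. The filter on dim probes kept a probe that was well above background in at least 1 line. Dim values in the other line or fraction therefore stayed among the tested genes, such as FN1 in AsPC1.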

Other observations

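Of the values in this part, the fit with lines as replicates and the choice of single genes outside called lists were made after the results were seen. Several single genes moved in the same direction in both lines although their list as a whole was not called. CD74, the invariant chain of antigen presentation, was higher in the AcTub-high fraction by 1.71 ± 0.07 in AsPC1 and 1.47 ± 0.00 in CFPAC (limma adjusted p = 1.66e-05 and 1.3e-05). The Notch target HES1 was at 0.93 and 0.76, the pluripotency factor POU5F1 at 1.24 and 0.55 at its brightest probe (-0.07 in CFPAC with the mean of all probes), and the tuft cell channel TRPM5 at 0.48 and 0.70. Vimentin VIM, an intermediate filament of mesenchymal cells, was lower by a log2 ratio of -0.91 ± 0.00 in AsPC1 and -1.69 ± 0.02 in CFPAC, while the mesenchymal list had medians of 0.07 and -0.04 (adjusted p = 0.316 and 0.689). The heat shock list, called in AsPC1, had a median of -0.09 in CFPAC with 9 of 20 lower and 3 higher (adjusted p = 0.0811), but was called there with median centring (adjusted p = 0.0288) and with no filter on dim probes (adjusted p = 0.0178).

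The following lists were not called in either line, except that epithelial genes were called in AsPC1 with no filter on dim probes (adjusted p = 0.00623) and without the first AsPC1 array (adjusted p = 0.0496). Their medians in AsPC1 and CFPAC were 0.23 and -0.09 for epithelial genes, 0.17 and -0.09 for the unfolded protein response, -0.04 and -0.04 for microtubule-associated proteins, 0.06 and -0.04 for cholesterol synthesis, 0.11 and 0.13 for oxidative phosphorylation, and -0.12 and -0.02 for Wnt targets. They were -0.09 and -0.14 for YAP targets, 0.04 and 0.07 for Notch genes, 0.16 and 0.01 for p53 targets, 0.03 and -0.08 for the primary cilium, 0.06 and 0.06 for the motile cilium, -0.03 and -0.01 for Hedgehog genes and 0.06 and -0.07 for glycolysis. The hypoxia, NF-kB and immediate early lists, called in AsPC1, had medians of 0.04, 0.12 and -0.10 in CFPAC (adjusted p = 0.98, 0.374 and 0.226). Median, mean and camera direction did not share one sign for the Hedgehog, stem cell and Wnt lists in AsPC1, and for the cholesterol, epithelial, fibroblast, Hedgehog, hypoxia, neural, oxidative phosphorylation, p53 and tuft lists in CFPAC; none of these was called there. With each line taken as 1 replicate, camera called 12 lists, among them histones, both cell cycle lists, ribosome assembly, ribosomal proteins, proteasome, ductal markers and mitochondrially encoded genes.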
